A study of Mus musculus with 12 samples.

How the data were processed

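RNA was measured by bulk sequencing in 12 subcutaneous tumours of the mouse melanoma cell line B16/F10 grown in C57BL/6 mice, with 3 tumours in each of 4 groups. The tumour cells were Cas9 control cells or cells in which XRN1 had been targeted with a single guide RNA. Mice received mock treatment or GVAX, a vaccine of irradiated tumour cells that secrete a granulocyte-macrophage growth factor, together with an antibody against PD-1, a receptor that restrains T cells. Per the labels' protocols, 100000 cells were injected, GVAX was given on days -1 and 1, and 100 µg of antibody was given from day 4, every 3 days, for 4 doses. The 3 largest tumours of each group were sequenced as paired 150-base reads, so each group is a selection by size and not a random sample of its tumours. Groups and replicate numbers came from the sample titles and characteristics. Replicate numbers run on from group to group, so they pair no tumours, and no batch or date is given in the labels. The tumours are separate tumours, but whether each came from its own mouse is not stated. The limma p-values of single genes thus measure the spread between tumours.

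The deposited table holds 1 normalized signal value per gene and library for 54307 genes, with Ensembl identifiers, symbols and gene coordinates per the file headers. The submitters' processing notes name Salmon, DESeq2 and the GRCm39 build, with no versions or roles, and the annotation release is not given in the sources used here. The values are not whole numbers. Their median ratio to the gene-wise geometric mean was 1.011 in all 12 libraries, which is what division by median-of-ratios size factors leaves behind. In many genes with low values the values lie on steps of 0.516 to 2.194, as 1 read divided by a size factor would give. Of values below 20 steps, 22% to 62.4% per library lay within 0.01 step of a whole number, so whole reads could not be recovered and no count test was run. The plan had allowed for counts. Because the unit was a normalized signal, the test planned for normalized values was used in its place. Dividing the library totals of 18600000 to 57240000 by the step gives roughly 16100000 to 37400000 reads per library, an estimate of depth that carries no interval. A value of 0 is reported as listed at 0 and is given no fold.

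Values were transformed to log2(value + 1), and genes with a value of 1 or more in at least 3 libraries were tested, which left 19062. The file lists 29641 genes at 0 in all 12 libraries. Fold changes are on this log2 scale, which understates the change of genes with low values. limma 3.58.1 in R 4.3.3 was fitted to all 12 libraries with a mean for each of the 4 groups and an intensity trend, so the 4 groups share 1 estimate of spread per gene. The 7 contrasts were the knockout-labelled group against control under mock and under treatment, treatment against mock in control and in knockout-labelled tumours, the interaction, and the 2 averaged contrasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors of log2 fold changes are standard errors from limma, and errors of levels are SDs over 3 tumours.

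The 28 gene lists, the contrasts, the test and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were compared with all other tested genes by camera with a preset correlation of 0.01, adjusted over the 28 lists within each contrast. The preset treats members as nearly independent, so its p-values are too small where members move together from tumour to tumour. The estimated correlation was 0.16 for interferon-stimulated, 0.37 for macrophage, 0.61 for red blood cell and 0.96 for mitochondrial genes. camera with an estimated correlation and fry, which asks whether a list moves 1 way on balance, were run beside it. For each list, genes were also adjusted over the list alone. The lists cover markers of T cells, cytotoxic effectors, NK cells, B and plasma cells, macrophages and monocytes, dendritic cells, neutrophils, regulatory T cells, fibroblasts and matrix, endothelium, skin epithelium, adipocytes, skeletal muscle and red blood cells. They also cover immune checkpoints, type I interferon-stimulated genes, double-stranded RNA sensing, interferon-gamma-induced genes, MHC class I and class II presentation, NF-kB and inflammatory cytokines, melanocyte differentiation, proliferation, cytoplasmic RNA decay, the integrated stress response, hypoxia and glycolysis, immediate early and heat shock genes, and mitochondrially encoded genes. Some lists share a few members, at most 3 with all other lists together.

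For each contrast the rule named Xrn1, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose mean was at least 1, and up to 3 members of each list with the smallest p. Predicted models, genes with no symbol and single antigen receptor segments were left out of the names. Where no gene passed, the 3 with the smallest p in each direction were named with the statement that they did not pass. The text prints a part of the genes so named, and 1 result is not reported here. The file gives no strand or multi-mapping rule, so near-identical genes (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Apol9a and Apol9b, and the Gbp, Ifit and H2 families) and overlapping or antisense genes are uncertain one by one. A further 21 symbols belong to more than 1 tested gene. Coordinates are those of the file. A GENCODE vM21 annotation on the older GRCm38 build served, by gene identifier, for GC content and transcript length alone, and 99.9% of the genes used matched.

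Alternatives planned beforehand were pseudocounts of 0.1 and 5, no filter, a minimum of 5 and a stricter filter on values scaled to the library total, scaling to library totals, a melanocyte score as covariate, a minimum log2 fold change of 1, fits on the 2 groups compared only, and each library left out. Added after seeing the data were quantile normalization, totals without mitochondrial genes, limma array weights, the mitochondrial share as covariate, and leaving out control_GVAX_PD1 replicate 7 with XRN1KO_GVAX_PD1 replicate 12. The code was tested on simulated reads turned into values of the same kind, with 200 changed genes in each of 10 runs per contrast. With 18821 to 18877 genes per run, genes changed 4-fold were recovered in 68.1%, 71.1%, 67.4%, 67.6%, 57.9%, 78.3% and 77.6% of cases, in the order of the 7 contrasts above. Unchanged genes made up 0%, 30%, 6.59%, 2.65%, 3.75%, 3.2% and 11% of calls. The 30% stands for the knockout-labelled contrast under treatment, where groups of unequal spread share 1 estimate of spread, and fell to 0.14% in fits on the 2 groups alone. For 2-fold changes the recovered shares were 36.6%, 36.6%, 34%, 35.5%, 12%, 55.5% and 59.4%. The simulation went from 1 to 10 runs after the share of unchanged genes in that contrast was seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.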

Results

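Tumours of B16/F10, a pigmented mouse melanoma line, were profiled to ask how targeting XRN1 in the tumour cells changes gene expression in the tumour, with and without vaccine and checkpoint antibody treatment. XRN1 is the main cytoplasmic exonuclease that degrades RNA from its 5' end. The 12 libraries fall into 4 groups of 3 tumours: control under mock (control_mock replicates 1 to 3), XRN1 knockout under mock (XRN1KO_mock replicates 4 to 6), control under GVAX plus PD-1 antibody (control_GVAX_PD1 replicates 7 to 9) and XRN1 knockout under GVAX plus PD-1 antibody (XRN1KO_GVAX_PD1 replicates 10 to 12). Values were normalized signals, with totals of 18600000 to 57240000 and a rough depth of 16100000 to 37400000 reads per library. Between 13688 and 19593 genes were above 0. The number separated the mock groups, at 14781, 17067 and 18803 in control and 19384, 19430 and 19593 in knockout libraries. Under treatment it was 14427, 16136 and 14737 in control and 17059, 15811 and 13688 in knockout libraries. Pearson's r of log2 values across genes was 0.852 to 0.976 within groups and 0.789 to 0.959 between groups, where genes are not independent replicates.

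The mitochondrial share of the signal, which need not reflect tissue composition, was highest in treated knockout tumours. The mitochondrial genome took 7.35% ± 7.3 of the signal in control mock tumours, 5.09% ± 3.5 in knockout mock tumours, 13.8% ± 2.81 in treated control tumours and 48.2% ± 4.22 in treated knockout tumours (SD, n = 3 each). It ranged from 44.5% to 52.8% in the last group and was at most 15.7% in any other library. The first principal component held 32% of the variance and the second 17%, and XRN1KO_GVAX_PD1 replicate 12 lay farthest out on the second (187), followed by XRN1KO_GVAX_PD1 replicate 10 (-97.9) and control_GVAX_PD1 replicate 7 (77.03).

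Xrn1 (ENSMUSG00000032410, chromosome 9, 95836813 to 95939856, GRCm39) was higher, not lower, in the libraries labelled XRN1 knockout. Its normalized values were 221, 240 and 159 in control mock tumours and 476, 460 and 392 in knockout mock tumours. Under treatment they were 421, 218 and 340 in control and 603, 804 and 633 in knockout tumours. The log2 difference was 1.11 ± 0.30 (SE) under mock, which did not pass (limma, adjusted p = 0.056), 1.10 ± 0.30 under treatment (adjusted p = 0.019) and 1.10 ± 0.21 averaged over both (adjusted p = 0.0021). The interaction was -0.02 (adjusted p = 0.99). A gene-level value counts reads of the whole transcript and says nothing of small edits or of protein, so these libraries are called labelled XRN1 knockout, or knockout-labelled, throughout. Without control_GVAX_PD1 replicate 8 the treated difference had an adjusted p of 0.072, and without XRN1KO_GVAX_PD1 replicate 11 it was 0.066. With scaling to library totals it was 0.36 (adjusted p = 0.44), with quantile normalization 0.86 (adjusted p = 0.055), and with the 2 treated groups fitted alone its adjusted p was 0.11. The mock difference, at 1.11, had an adjusted p of 0.04, 0.036 and 0.047 without control_GVAX_PD1 replicates 7, 8 and 9 and of 0.046 without XRN1KO_GVAX_PD1 replicate 12, libraries that enter the shared spread alone.

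**Figure D1:**
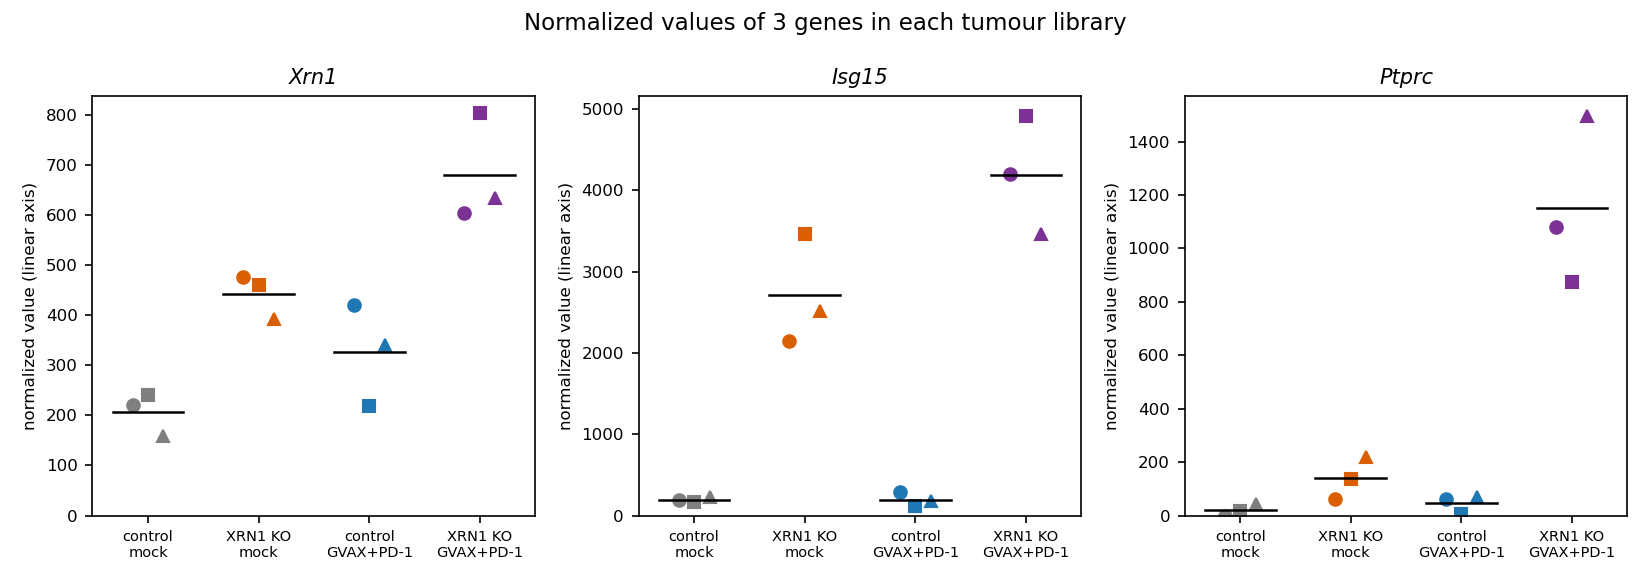
Normalized values (linear axis) of Xrn1, Isg15 and Ptprc in each of the 12 tumour libraries, with 1 symbol per library (circle, square and triangle in order of replicate number) and a line at the group mean. Xrn1 and Isg15 were higher in knockout-labelled tumours under both treatments, and Ptprc, a surface protein of leukocytes, averaged 1150 in treated knockout-labelled tumours against 19.8 to 140 in the other groups.

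The first comparison asked how knockout-labelled tumours differ from control tumours without treatment. Type I interferon-stimulated genes rose together: 26 of the 34 measured members were higher and 0 lower, with a median log2 difference of 3.48 (camera, adjusted p = 1.3e-34, and adjusted p = 0.011 with an estimated correlation). Isg15 (ENSMUSG00000035692, chromosome 4, 156283912 to 156285253), a ubiquitin-like protein induced by interferon, was 196 ± 25.4 in control and 2710 ± 678 in knockout-labelled tumours (SD, n = 3), a log2 difference of 3.76 ± 0.30 (SE, adjusted p = 5.9e-05). Ifit3, an interferon-induced antiviral protein, went from 152 ± 71.5 to 3120 ± 1380, and Usp18, a protease that removes Isg15 from proteins, differed by 4.53 ± 0.47 (adjusted p = 0.00032). Apol9a, an interferon-induced apolipoprotein L family gene, had the largest rise among genes with values in both groups, from 9.46 ± 12.3 to 1690 ± 263. Atp10b was listed at 0 in all 3 control tumours and averaged 634 in knockout-labelled tumours.

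Genes that sense double-stranded RNA and genes of interferon-gamma response were also higher as lists. The interferon-gamma scores overlapped, with 6.24 in XRN1KO_mock replicate 4 and 6.29 in control_mock replicate 1. Of 16 sensing genes 3 rose (Ifih1 and Ddx58, cytoplasmic RNA sensors, and Zbp1, a sensor of left-handed nucleic acid), with a list adjusted p of 0.014 and adjusted p = 0.25 with an estimated correlation. Of 26 interferon-gamma-induced genes 5 rose, among them Cxcl10, a chemokine that attracts T cells, at 2.52 ± 0.28 (adjusted p = 4e-04), with a list adjusted p of 0.00032 and adjusted p = 0.33 with an estimated correlation. MHC class I genes (1 of 19 rose, Tapbp) and MHC class II genes (1 of 12 rose, H2-DMb1, at -0.68 with a melanocyte score as covariate) passed as lists with adjusted p of 0.023 and 0.00015, and with adjusted p = 0.56 and adjusted p = 0.25 with an estimated correlation.

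Lists of macrophage, cytotoxic, dendritic cell and fibroblast genes were also higher. Of 22 macrophage and monocyte markers 2 rose, Mrc1, a mannose receptor, from 57.4 ± 17.7 to 587 ± 283, and Itgam, an integrin subunit (list adjusted p = 1.5e-08, and adjusted p = 0.23 with an estimated correlation). Ccl5, a chemokine made by T cells and macrophages, rose from 32.7 ± 10.4 to 823 ± 455. Of 17 cytotoxic effector genes it was 1 of 2 that rose, the other being Gzmc, a granzyme (list adjusted p = 0.00038, and adjusted p = 0.15 with an estimated correlation). Of 13 dendritic cell markers 0 passed, while the list did (adjusted p = 0.013, and adjusted p = 0.28 with an estimated correlation). Of 22 fibroblast and matrix genes 6 rose, among them the collagens Col1a1, from 771 ± 395 to 6680 ± 3890, and Col5a1, by 2.12 ± 0.30 (list adjusted p = 2.4e-09, and adjusted p = 0.22 with an estimated correlation). T cell markers had a median of 1.51 with 0 of 22 members past the test, and the list missed it (adjusted p = 0.054).

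In the pigment lineage, 8 of 22 melanocyte differentiation genes rose, led by Trpm1, a cation channel of melanocytes, from 720 ± 188 to 5530 ± 1000 (list adjusted p = 1.5e-08, and adjusted p = 0.077 with an estimated correlation). Rab38, which traffics pigment enzymes to melanosomes, rose from 1380 ± 326 to 4430 ± 254. Red blood cell genes fell: Hbb-bs, a beta globin, was 169000 ± 130000 in control and 1110 ± 499 in knockout-labelled tumours. Of the 7 members 5 passed, 0 of them higher (median -5.56, list adjusted p = 3.1e-14, and adjusted p = 0.05 with an estimated correlation). Tnfrsf9, a costimulatory receptor of activated T cells, went from 2080 ± 1970 to 52.4 ± 32.5. Proliferation genes were lower as a list (median -0.28, adjusted p = 5.4e-06, and adjusted p = 0.027 with an estimated correlation), although 0 of 30 members passed alone. Adjusted over the list alone, the members called were 32 interferon-stimulated, 6 double-stranded RNA sensing, 6 interferon-gamma-induced, 2 MHC class I, 5 MHC class II, 14 macrophage, 3 cytotoxic, 13 fibroblast, 10 melanocyte, 7 red blood cell and 0 proliferation genes.

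The other lists did not pass under mock. Their adjusted p was 0.091 for NK cells, 0.35 for B and plasma cells, 0.9 for neutrophils, 0.3 for regulatory T cells, 0.42 for immune checkpoints, 0.091 for NF-kB genes, 0.18 for the integrated stress response, 0.9 for hypoxia, 0.35 for endothelium, 0.75 for skin, 0.23 for adipocytes, 0.42 for muscle, 0.22 for immediate early genes and 0.29 for mitochondrial genes. For cytoplasmic RNA decay, the pathway in which XRN1 acts, the adjusted p was 0.091. Within it Ddx6, a helicase of mRNA decapping, rose by 0.96 ± 0.20 (adjusted p = 0.02), and Lsm5 and Lsm3, members of the ring that binds the 3' end of decaying mRNA, fell by 0.99 and 0.66. Within the stress list Atf4, its transcription factor, rose from 8360 ± 992 to 17600 ± 1480, while Shmt2, a mitochondrial serine enzyme, fell by 0.70 ± 0.17 (adjusted p = 0.032).

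In all, 542 genes were higher and 209 lower in knockout-labelled mock tumours, out of 19062. The groups did not overlap in any of the 751, and 6994 genes had groups that did not overlap, against the 10% of genes that chance gives for 3 against 3. The count was 2854 when the 2 groups were fitted alone, 3956 with array weights, 2 with a melanocyte score as covariate, a score that itself separates the groups, and 1369 without control_GVAX_PD1 replicate 7 and XRN1KO_GVAX_PD1 replicate 12. Without control_mock replicate 1, 2 or 3 it was 302, 283 or 363, and without XRN1KO_mock replicate 4, 5 or 6 it was 258, 200 or 214.

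**Figure D2:**
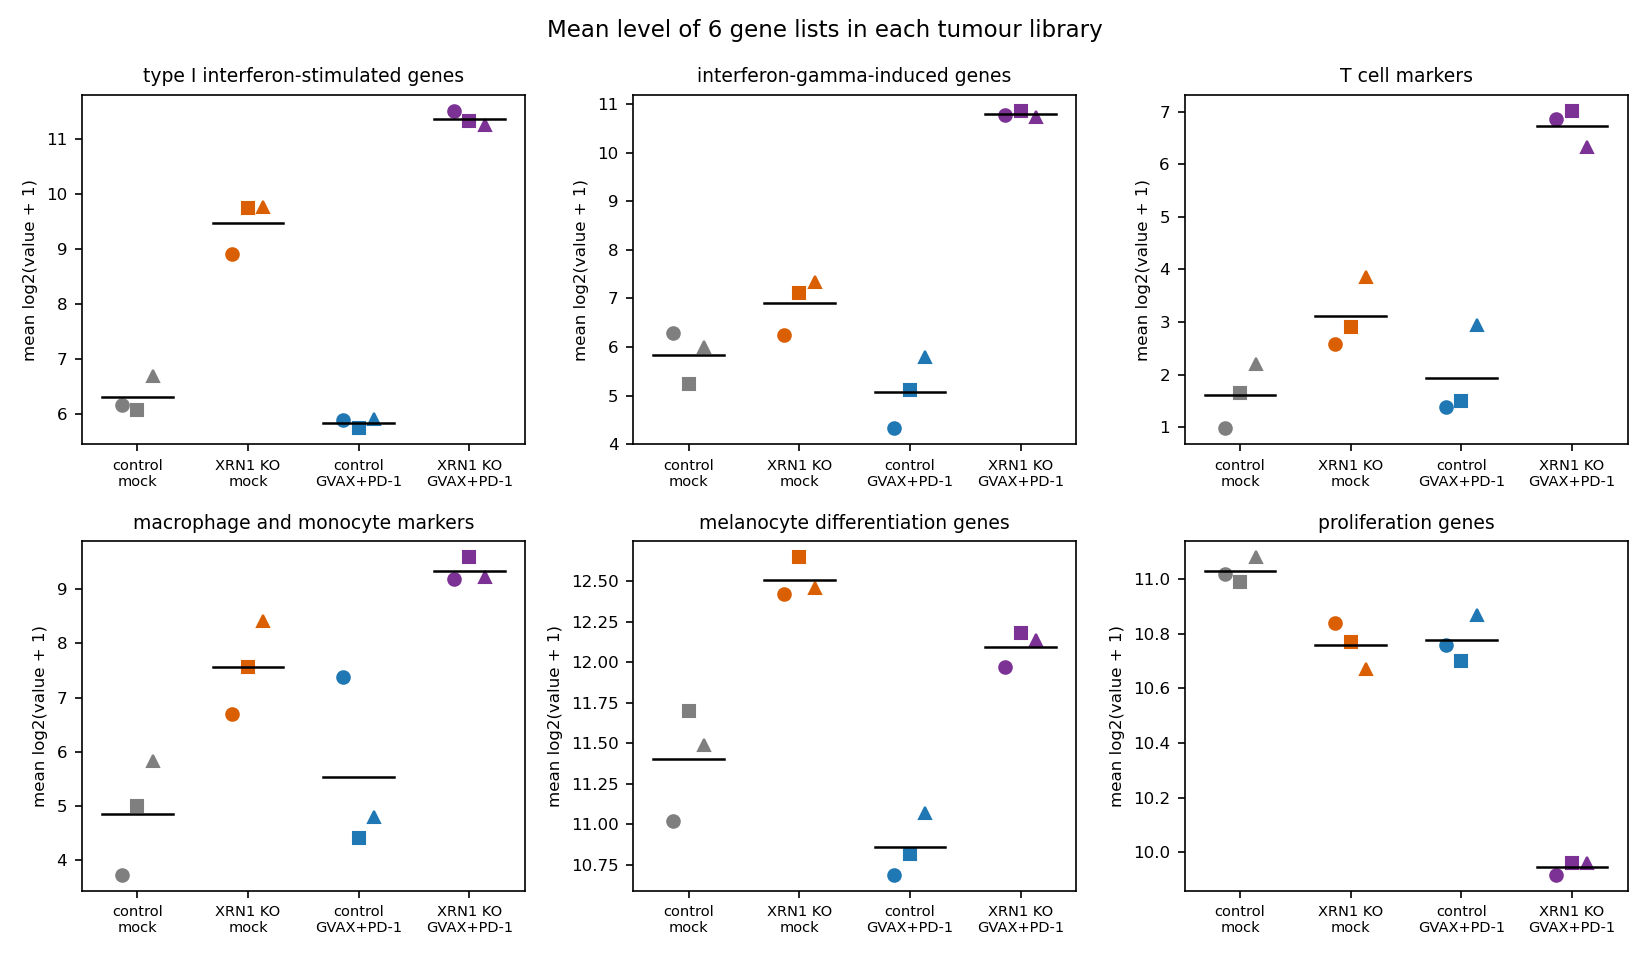
Mean log2(value + 1) over the members of 6 gene lists in each tumour library, with 1 symbol per library (circle, square and triangle in order of replicate number) and a line at the group mean, on axes that do not start at 0. The interferon-stimulated list was higher in all 6 knockout-labelled libraries, with 8.92 as its lowest mean there and 6.7 as its highest in control libraries, and the proliferation list was lowest in treated knockout-labelled libraries.

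The next comparison set knockout-labelled against control tumours when both had received GVAX plus PD-1 antibody. Interferon-stimulated genes rose in 33 of 34 cases, with a median of 5.30 (adjusted p = 3.3e-33, and adjusted p = 0.0065 with an estimated correlation). Interferon-gamma-induced genes rose in 23 of 26, with a median of 5.41 (adjusted p = 2.6e-23, and adjusted p = 0.026 with an estimated correlation). Cxcl10 (ENSMUSG00000034855, chromosome 5, 92494497 to 92496748) was 84.3 ± 21.3 in control and 3210 ± 182 in knockout-labelled tumours, and Irf7, a transcription factor that amplifies interferon production, differed by 6.57 ± 0.45. T cell markers rose in 15 of 22 cases (median 5.05, adjusted p = 7.5e-09, and adjusted p = 0.045 with an estimated correlation). Over the 12 T cell markers above 0 in both groups the median was 3.88. Cd8a, the coreceptor of cytotoxic T cells, was 10.1 ± 12.9 against 400 ± 96.7. Of 17 cytotoxic effector genes 12 rose (adjusted p = 3.2e-08, and adjusted p = 0.026 with an estimated correlation). Gzmb, the main granzyme of killer cells, and Ifng, the interferon-gamma gene, were listed at 0 in all 3 treated control tumours and averaged 372 and 72.4 in the knockout-labelled ones.

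Lists of macrophage, NK, B and plasma cell and dendritic cell markers were higher too. Of 22 macrophage markers 16 were higher, among them C1qb, a complement subunit, from 395 ± 414 to 6280 ± 1090, and Adgre1, the F4/80 antigen, from 43.7 ± 11 to 1170 ± 170. Members that rose numbered 4 of 10 for NK cells, 3 of 10 for B and plasma cells, 5 of 13 for dendritic cells, 15 of 19 for MHC class I, 7 of 12 for MHC class II, 9 of 16 for double-stranded RNA sensing and 3 of 19 for NF-kB genes. Among immune checkpoints 6 of 14 rose, such as Cd274, the ligand of PD-1, from 211 ± 153 to 1140 ± 163, and Tnfrsf9 fell. These lists had adjusted p of 1.5e-08 for macrophages, 0.00051 for NK cells, 0.026 for B cells, 0.00067 for dendritic cells, 4.4e-09 for MHC class I, 2.7e-06 for MHC class II, 2.7e-06 for RNA sensing, 0.017 for NF-kB and 0.00051 for checkpoints. With an estimated correlation the adjusted p was, in that order, 0.13, 0.17, 0.12, 0.12, 0.13, 0.12, 0.045, 0.27 and 0.079. With scaling to library totals 12 MHC class I genes rose and 3 fell, and 7 RNA sensing genes rose and 1 fell (median 0.64 against 1.37).

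Proliferation genes and the hypoxia and glycolysis genes went the other way. Of 30 proliferation genes 23 fell and 1 rose (median -0.86, adjusted p = 5.6e-13, and adjusted p = 0.0031 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was 5840 ± 505 in control and 1960 ± 326 in knockout-labelled tumours, and Mcm2, part of the replicative helicase, differed by -1.37 ± 0.16. Of 24 hypoxia and glycolysis genes 10 fell, Eno1 and Tpi1 among them, and 1 rose (adjusted p = 0.0013, and adjusted p = 0.38 with an estimated correlation). The hypoxia scores of the groups overlapped. They were 11.55, 11.50 and 10.79 in XRN1KO_GVAX_PD1 replicates 10, 11 and 12. In control_GVAX_PD1 replicates 7, 8 and 9 they were 12.38, 11.64 and 11.48. Red blood cell genes fell in 6 of 7 cases (median -6.70, adjusted p = 1.5e-08, and adjusted p = 0.079 with an estimated correlation). Endothelial markers fell in 5 of 15 with 1 rise (adjusted p = 0.00094, and adjusted p = 0.31 with an estimated correlation). Melanocyte genes rose in 11 of 22 cases (median 0.84, and 0.11 with scaling to library totals; adjusted p = 6.6e-05, and adjusted p = 0.12 with an estimated correlation). Fibroblast genes rose in 10 of 22 cases with 1 fall (adjusted p = 0.0024, and adjusted p = 0.36 with an estimated correlation). With scaling to library totals 6 melanocyte genes rose and 4 fell, and 7 fibroblast genes rose and 4 fell. Mitochondrially encoded genes rose in 10 of 13 (adjusted p = 7.8e-06, and adjusted p = 0.3 with an estimated correlation), beside the mitochondrial share of 48.2% against 13.8%. With that share as covariate mt-Nd2 turned to -3.63.

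Counting only members that moved with their list, adjusted over the list alone, the genes that rose were 33 interferon-stimulated, 25 interferon-gamma-induced, 20 T cell, 15 cytotoxic, 19 macrophage, 8 NK, 4 B cell, 6 dendritic, 16 MHC class I, 10 MHC class II, 11 RNA sensing, 5 NF-kB, 11 checkpoint, 11 melanocyte, 12 fibroblast and 12 mitochondrial genes. Those that fell, counted the same way, were 23 proliferation, 11 hypoxia, 7 red blood cell and 6 endothelial genes. The lists that did not pass were neutrophils (adjusted p = 0.49), regulatory T cells (0.14), RNA decay (0.088), integrated stress response (0.16), skin (0.3), adipocytes (0.57), muscle (0.37) and immediate early genes (0.76), the last with a median of -0.03 and a mean of 0.32. The muscle score was 9.14 in XRN1KO_GVAX_PD1 replicate 10, 1.74 and 0.51 in replicates 11 and 12, and at most 5.39 in the other groups. In all, 2242 genes were higher and 1728 lower, and in 3754 of the 3970 the groups did not overlap. With scaling to library totals the balance turned, and most of the 5408 called genes were lower. The 2 groups fitted alone gave 1185 genes. In simulated data with 200 changed genes per run, 30% of the calls of this contrast were unchanged genes, 56.4 per run. That share depends on how many genes change, so it need not carry over to the 3970 calls. With the mitochondrial share or the melanocyte score as covariate, each of which nearly coincides with a group, limma called 0 genes.

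The genes that differed between knockout-labelled and control tumours overlapped between mock and treatment. The differences themselves share no library, but the calls share 1 estimate of spread per gene from all 12 libraries. Genes of low spread are thus favoured in both, so more overlap than for independent lists would arise without any common effect. Both comparisons also set the same injected cells against each other, so any difference between those cells recurs. Of the genes called under mock, 360 of 542 were also higher under treatment, where independent lists would share 63.7, and 161 of 209 were also lower, where independent lists would share 18.9. Across the 19062 genes the log2 differences had Pearson's r of 0.509 and Spearman's rho of 0.459, and across the 751 genes called under mock 0.823 and 0.817. These are correlations across genes, which are not independent replicates.

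**Figure D3:**
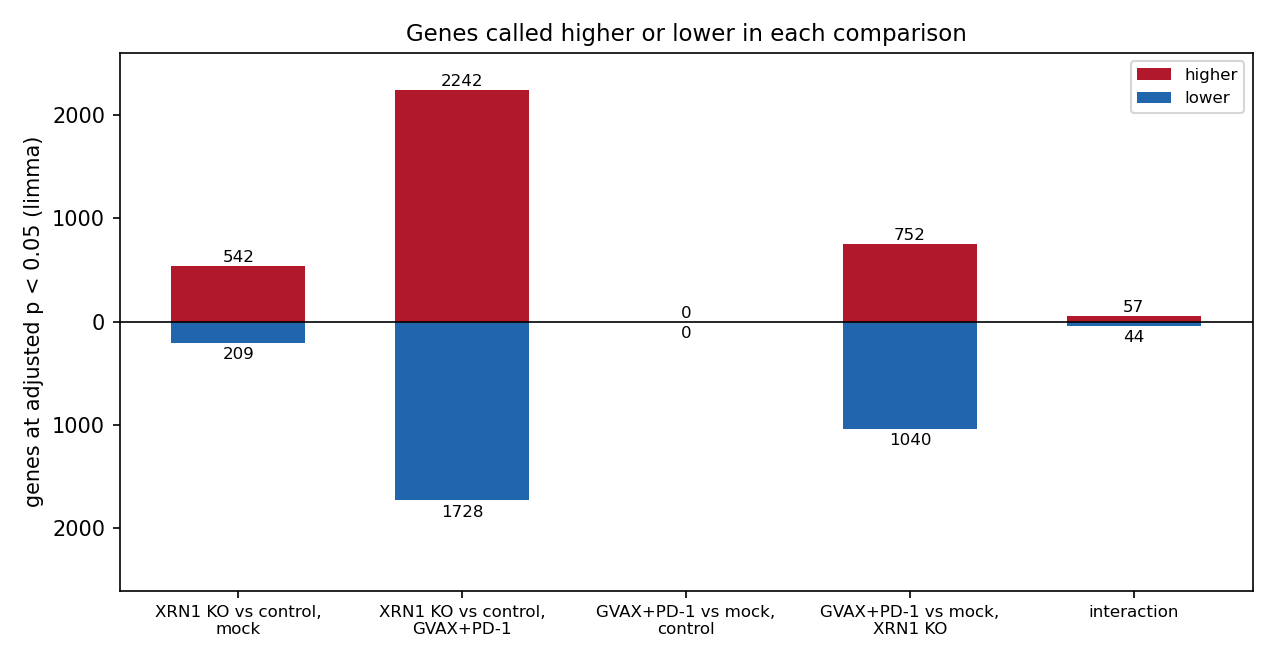
Genes called higher (above 0) or lower (below 0) in 5 comparisons at an adjusted p under 0.05 in limma, with the number beside each bar. The bars show 542 and 209 genes for knockout-labelled against control under mock, 2242 and 1728 under treatment, 0 for treatment in control tumours, 752 and 1040 for treatment in knockout-labelled tumours and 57 and 44 for the interaction.

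Treatment was then compared with mock within control tumours. limma called 0 genes at an adjusted p under 0.05, while 1275 passed an unadjusted p under 0.05 (525 higher and 750 lower), against 953 by chance. The smallest adjusted p was 0.053, for Ccdc47, a protein of the endoplasmic reticulum, at 1710 ± 186 under mock and 556 ± 24 under treatment. Beside it the genes with the smallest p were Grik3 and Slc38a10, with lower values under treatment, and Klhl30, Fxyd5 and Wfdc21, with higher values, and none of these passed. Groups did not overlap in 1815 genes, and 10% would not by chance. The tests with 1 to 4 calls were quantile normalization with 3, array weights with 4, a pseudocount of 5 with 2, and library totals, totals without mitochondrial genes and both stricter filters with 1 each. Without XRN1KO_GVAX_PD1 replicate 11, which enters the shared spread alone, 1 gene was called.

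As lists, 10 of 28 passed camera with the preset correlation, 0 with an estimated correlation and 1 with fry. Mitochondrial genes (median 1.78, adjusted p = 3.5e-10), red blood cell genes (1.91, adjusted p = 2.5e-05), hypoxia genes (0.41, adjusted p = 2.5e-05), neutrophil markers (1.53, adjusted p = 0.032) and fibroblast genes (0.31, adjusted p = 0.035) were higher. With an estimated correlation their adjusted p was 0.54, 0.54, 0.76, 0.76 and 0.76. The neutrophil score (mean log2) was 5.80, 3.62 and 1.30 in control_GVAX_PD1 replicates 7, 8 and 9 against 2.13 to 2.55 under mock. The fibroblast score was 7.44, 6.60 and 6.22 against 5.80 to 6.73, so replicate 9 had a lower neutrophil score than each mock tumour, and replicate 7 alone had a higher fibroblast score than each. With scaling to library totals the hypoxia and fibroblast medians were 0.06 and 0.00. Melanocyte genes (-0.32, adjusted p = 1.4e-05), proliferation genes (-0.24, adjusted p = 6.8e-05), interferon-gamma-induced genes (-0.65, adjusted p = 0.014), MHC class I genes (-0.29, adjusted p = 0.048) and interferon-stimulated genes (-0.27, adjusted p = 0.049) were lower. With an estimated correlation their adjusted p was 0.38, 0.098, 0.76, 0.76 and 0.76. The MHC class I score was 9.56, 9.42 and 10.96 in replicates 7, 8 and 9 of control_GVAX_PD1 against 10.13 to 10.55 under mock, so replicate 9 was above each mock tumour. Scores of the mitochondrial, red blood cell, hypoxia, interferon-gamma-induced and melanocyte lists also overlapped between treated and mock control tumours. Those of the proliferation and interferon-stimulated lists did not. No member of any list passed over all genes. Adjusted over the list alone, 2 red blood cell genes and 1 macrophage marker rose, and 4 melanocyte, 3 interferon-stimulated and 1 MHC class I genes fell. Without control_mock replicate 3, control_GVAX_PD1 replicate 7 or control_GVAX_PD1 replicate 8, the lists that passed numbered 6, 5 and 6.

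Within knockout-labelled tumours, treatment was accompanied by higher immune and lower proliferation genes. Interferon-gamma-induced genes rose in 20 of 26 cases (median 3.94, adjusted p = 1e-24, and adjusted p = 0.031 with an estimated correlation). Gbp4 (ENSMUSG00000079363, chromosome 5, 105263633 to 105287452), an interferon-induced GTPase, was 83.9 ± 52.9 under mock and 6230 ± 382 under treatment, and Irf8, a transcription factor of myeloid cells, went from 231 ± 60.8 to 3710 ± 118. T cell markers rose in 10 of 22 cases, such as Lck, the kinase of the T cell receptor, from 42.5 ± 11 to 553 ± 101 (list adjusted p = 3.5e-11, and adjusted p = 0.035 with an estimated correlation). Interferon-stimulated genes rose in 14 of 34 cases (adjusted p = 8.5e-17, and adjusted p = 0.035 with an estimated correlation), with a median of 1.83 that was 0.55 with scaling to library totals, where 6 rose and 2 fell. Checkpoint genes rose in 3 of 14, namely Cd274, Tox and Tigit (adjusted p = 1.7e-05, and adjusted p = 0.037 with an estimated correlation). Of 30 proliferation genes 19 fell and 0 rose (median -0.94, adjusted p = 9.1e-15, and adjusted p = 0.002 with an estimated correlation), with Rrm2 at 5390 ± 255 under mock and 1960 ± 326 under treatment.

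Cytotoxic, NK, B and plasma cell, macrophage, dendritic cell and NF-kB lists rose with the preset correlation. Members that rose were 4 of 17 cytotoxic genes, Klri2 alone of 10 NK markers, Jchain and Ighm of 10 B and plasma cell markers (Ighm at -2.38 with the mitochondrial share as covariate), 4 of 22 macrophage markers, Xcr1 and Siglech of 13 dendritic cell markers, and Tnf alone of 19 NF-kB genes. The adjusted p was 3.5e-05, 0.0024, 0.0024, 2.7e-05, 0.0071 and 0.013 for these 6 lists, and with an estimated correlation the adjusted p was 0.055, 0.24, 0.052, 0.24, 0.23 and 0.24. The NK score was 6.07, 5.80 and 2.71 in XRN1KO_GVAX_PD1 replicates 10, 11 and 12 against 1.81 to 2.93 under mock, so replicate 12 did not exceed the mock tumours. MHC class I genes rose in 12 cases and fell in 3, among the latter Calr, a chaperone that was at 0.39 with the mitochondrial share as covariate (adjusted p = 5.6e-08, and adjusted p = 0.22 with an estimated correlation). MHC class II genes rose in 6 and fell in 1 (adjusted p = 0.00028, and adjusted p = 0.23 with an estimated correlation). With scaling to library totals 4 class I genes rose and 3 fell (median 0.32 against 1.60), 3 class II genes rose and 2 fell, 1 macrophage marker rose and 1 fell, and the NF-kB median was 0.07. The double-stranded RNA sensing list had a median of 1.05 that turned to -0.23 with scaling to library totals (5 of 16 rose, adjusted p = 3.3e-05, and adjusted p = 0.055 with an estimated correlation). The immediate early list had a median of 0.48 that turned to -0.79 with that scaling (3 of 18 rose, adjusted p = 0.035, and adjusted p = 0.41 with an estimated correlation).

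All 13 mitochondrially encoded genes rose, mt-Nd2 from 53600 ± 36100 to 1550000 ± 411000 (list adjusted p = 1.2e-17, and adjusted p = 0.092 with an estimated correlation), beside mitochondrial shares of 5.09% and 48.2%. Melanocyte genes fell in 5 of 22 cases, among them Pmel, which forms the fibrils of melanosomes, by 1.77 (list adjusted p = 0.025, and adjusted p = 0.33 with an estimated correlation), and with the mitochondrial share as covariate Pmel was at 1.55 and mt-Nd2 at -3.62. With scaling to library totals 18 melanocyte genes fell (median -1.75 against -0.47). Endothelial markers fell in 3 of 15 cases (adjusted p = 0.037, and adjusted p = 0.52 with an estimated correlation). Adipocyte markers had 0 of 9 called with a list adjusted p of 0.039 and adjusted p = 0.22 with an estimated correlation. Alb, the serum albumin gene of liver, was 1.85 ± 1.61 under mock and 439 ± 224 under treatment. The other lists had adjusted p of 0.087 for red blood cells, 0.11 for regulatory T cells, 0.16 for hypoxia, 0.39 for the integrated stress response, 0.43 for RNA decay, 0.44 for neutrophils, 0.7 for skin, 0.7 for muscle and 0.9 for fibroblasts.

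Of members that moved with their list, adjusted over the list alone, the genes that rose were 23 interferon-gamma-induced, 23 interferon-stimulated, 16 T cell, 8 cytotoxic, 4 NK, 4 B cell, 5 macrophage, 4 dendritic, 5 checkpoint, 13 MHC class I, 7 MHC class II, 6 RNA sensing, 1 NF-kB, 3 immediate early and 13 mitochondrial genes. Those that fell, on the same count, were 24 proliferation, 7 melanocyte and 4 endothelial genes. In all, 752 genes rose and 1040 fell, and the groups did not overlap in 1789 of the 1792. The balance depended on scaling: library totals gave 8303 genes with 3.91% of them higher, and totals without mitochondrial genes 3030 with 15.9% higher. Array weights gave 3141 genes, the melanocyte score as covariate 252 and the mitochondrial share as covariate 0. Without XRN1KO_mock replicate 4, 5 or 6 the count was 522, 563 or 905.

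The interaction asked whether treatment changed knockout-labelled tumours differently from control tumours. Gbp4 changed more in knockout-labelled tumours, with an interaction of 6.63 ± 0.74 (log2, SE, adjusted p = 0.0038), as did Irf8 (3.42 ± 0.36, adjusted p = 0.0036) and Irgm1, an interferon-induced GTPase (3.53 ± 0.45, adjusted p = 0.0085). The same held for Cxcl10 (2.74 ± 0.40, adjusted p = 0.011), H2-T23, a nonclassical MHC class I gene (2.26 ± 0.30, adjusted p = 0.0087), and Lck (4.74 ± 0.67, adjusted p = 0.01). In control tumours Gbp4 was 54.1 ± 3.21 under mock and 51.1 ± 24.4 under treatment, and Irf8 was 207 ± 5.74 and 323 ± 68.9. Car6, a secreted carbonic anhydrase, had the largest negative interaction apart from Tenm4, at -2.72 ± 0.32 (adjusted p = 0.0051), being 19100 ± 1530 in knockout-labelled mock tumours and 3580 to 5220 on average in the other 3 groups. Fscn1, an actin bundling protein, and Cited1, a transcriptional coactivator, had interactions of -2.06 and -1.87, and Rrm2 had -1.31 (adjusted p = 0.037). Xrn1 had none that passed.

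By list, 16 of 28 passed, 8 of them with an estimated correlation. Interferon-gamma-induced genes had 11 of 26 members called and a median of 3.54 (adjusted p = 3.5e-30, and adjusted p = 0.017 with an estimated correlation). Interferon-stimulated genes had 6 of 34 called and a median of 1.95 (adjusted p = 3.1e-19, and adjusted p = 0.025 with an estimated correlation), and T cell markers 1 of 22, Lck, and 3.10 (adjusted p = 1.6e-08, and adjusted p = 0.044 with an estimated correlation). Proliferation genes had 2 of 30 called, Rrm2 and Tyms, and a median of -0.67 (adjusted p = 8.1e-09, and adjusted p = 0.013 with an estimated correlation). Cytotoxic genes (3.34), B cell markers (3.18) and checkpoint genes (2.11) passed with 0 members called, with adjusted p of 2.8e-05, 0.00081 and 9.7e-05, and adjusted p = 0.048, 0.044 and 0.044 with an estimated correlation. The RNA sensing list, with Zbp1 alone called, had a median of 0.85 that turned to -0.07 with scaling to library totals (adjusted p = 2.5e-06, and adjusted p = 0.044 with an estimated correlation). MHC class I (4.4e-10), MHC class II (0.00073), macrophage (0.0031), NK (0.0066), dendritic (0.047), mitochondrial (2.2e-09), hypoxia (0.00034) and endothelial genes (0.0022) passed with these adjusted p, and with an estimated correlation the adjusted p was 0.16, 0.32, 0.45, 0.37, 0.39, 0.27, 0.42 and 0.42. The last 2 had negative medians, and the dendritic median of 1.16 was 0.19 with scaling to library totals and -0.59 over the 8 members above 0 in every group. Adjusted over the list alone, and counting only members that moved with their list, those called higher were 22 interferon-gamma-induced, 21 interferon-stimulated, 5 T cell, 4 cytotoxic, 2 B cell, 3 checkpoint, 6 RNA sensing, 12 MHC class I, 1 MHC class II, 0 macrophage, 1 NK, 3 dendritic and 13 mitochondrial genes. Members called lower, again over the list alone, were 17 proliferation, 2 hypoxia and 1 endothelial genes.

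The interaction held 57 positive and 44 negative genes, 101 in all, with 2647 at an unadjusted p under 0.05. The count was 54 and 222 with pseudocounts of 0.1 and 5, 36 without a filter, 2322 with library totals (4.13% positive), 162 with quantile normalization, 392 with array weights, 48 with the melanocyte covariate and 0 with the mitochondrial covariate. Without control_mock replicates 1, 2 and 3 it was 30, 30 and 18, without XRN1KO_mock replicates 4, 5 and 6 it was 5, 13 and 25, without control_GVAX_PD1 replicates 7 and 9 it was 65 and 219, and without XRN1KO_GVAX_PD1 replicate 11 it was 30.

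Averaged over both treatments, knockout-labelled tumours had 2627 higher and 1674 lower genes than control tumours, with groups of 6 that did not overlap in 1698 of the 4301. With scaling to library totals the balance turned here too, and most of the 4290 called genes were lower. Interferon-stimulated genes rose in 33 of 34 cases (adjusted p = 6.1e-34, and adjusted p = 0.0061 with an estimated correlation), Isg15 by 4.14 ± 0.21 (SE) and Ifit3 by 5.36 ± 0.29. Shisa2, a regulator of growth factor signalling, Trim71, a regulator of mRNA in stem cells, and Hbb-bs had differences of -6.27 ± 0.63, -5.94 ± 0.74 and -6.70 ± 0.57. Cytotoxic genes rose in 12 of 17 cases (adjusted p = 2e-07, and adjusted p = 0.041 with an estimated correlation), interferon-gamma-induced genes in 23 of 26 (adjusted p = 7.1e-18, and adjusted p = 0.041 with an estimated correlation). Proliferation genes fell in 19 of 30 with 1 rise (adjusted p = 1.7e-12, and adjusted p = 0.0036 with an estimated correlation). The list of cytoplasmic RNA decay genes was lower, with 3 members up and 7 down (median -0.24, adjusted p = 0.048, and adjusted p = 0.11 with an estimated correlation). A further 15 lists passed with the preset correlation and not with an estimated one. Adjusted over the list alone, 33 interferon-stimulated, 13 cytotoxic and 24 interferon-gamma-induced genes rose, 24 proliferation genes fell and 1 rose, and 4 RNA decay genes rose and 7 fell. The count was 2439 with a minimum log2 change of 1, and with the melanocyte and mitochondrial covariates it was 0 and 330.

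Averaged over control and knockout-labelled tumours, treatment was accompanied by 317 higher and 491 lower genes, with groups that did not overlap in 126 of the 808. The average joins unlike effects, as limma called 0 genes for treatment in control tumours and 1792 in knockout-labelled tumours. The median of interferon-gamma-induced genes was -0.65 in control and 3.94 in knockout-labelled tumours, and that of interferon-stimulated genes -0.27 and 1.83. Irf8 had a called interaction of 3.42. Irf8 rose by 2.32 ± 0.18 (adjusted p = 8e-05), Rgs2, a regulator of G protein signalling, by 1.61 ± 0.26 (adjusted p = 0.0069) and Adgre1 by 2.85 ± 0.50 (adjusted p = 0.01). Prom1, a surface glycoprotein, fell by 3.67. Of 30 proliferation genes 16 fell (adjusted p = 5.5e-16, and adjusted p = 0.0014 with an estimated correlation), the 1 list of 18 that also passed with an estimated correlation. Interferon-gamma-induced genes rose in 10 of 26 cases (adjusted p = 3e-15, and adjusted p = 0.088 with an estimated correlation). Among the medians that turned with scaling to library totals were those of 5 lists: interferon-stimulated genes from 0.74 to -0.07, RNA sensing from 0.20 to -0.62, MHC class I from 0.76 to -0.05, NF-kB from 0.51 to -0.14 and immediate early genes from 0.33 to -0.49. RNA sensing also turned to -0.13 with totals without mitochondrial genes. With an estimated correlation the adjusted p of these 5 lists was 0.12, 0.24, 0.3, 0.24 and 0.38. Adjusted over the list alone, 22 proliferation genes fell and 16 interferon-gamma-induced genes rose. The count was 7643 with library totals (2.84% higher), 2601 with totals without mitochondrial genes (10.3% higher), 1925 with array weights, 1240 without control_GVAX_PD1 replicate 7 and XRN1KO_GVAX_PD1 replicate 12, 415 with a minimum log2 change of 1, and 1 and 0 with the melanocyte and mitochondrial covariates. Without control_mock replicate 2 or 3 it was 276 or 329, and without XRN1KO_mock replicate 4, 5 or 6 it was 140, 195 or 419.

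Differences between knockout-labelled and control tumours were not spread evenly over the genome, a view of the data chosen after the values were seen. Among genes with a mean log2 value of 7 or more, those on chromosome 15 had a median log2 difference of 0.55 under mock and 0.38 under treatment (400 genes), those on chromosome 12 -0.46 and -0.43 (355 genes), those on chromosome 6 -0.20 and -0.39 (486 genes) and those on chromosome 9 0.17 and 0.11 (577 genes). On each of these 4 chromosomes the median of centred values separated all 6 knockout-labelled from all 6 control libraries (exact permutation test, two-sided, adjusted p = 0.011 over 20 chromosomes, where the smallest unadjusted p that 924 splits allow is 0.0022). Chromosome X had an adjusted p of 0.035 by the same exact test, with libraries that overlapped. On chromosome 9 the 74 such genes between 70 and 95 Mb, a segment chosen after its values were seen, had medians of 1.00 under mock and 0.93 under treatment. Xrn1 lies just beyond its upper end.

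**Figure D4:**
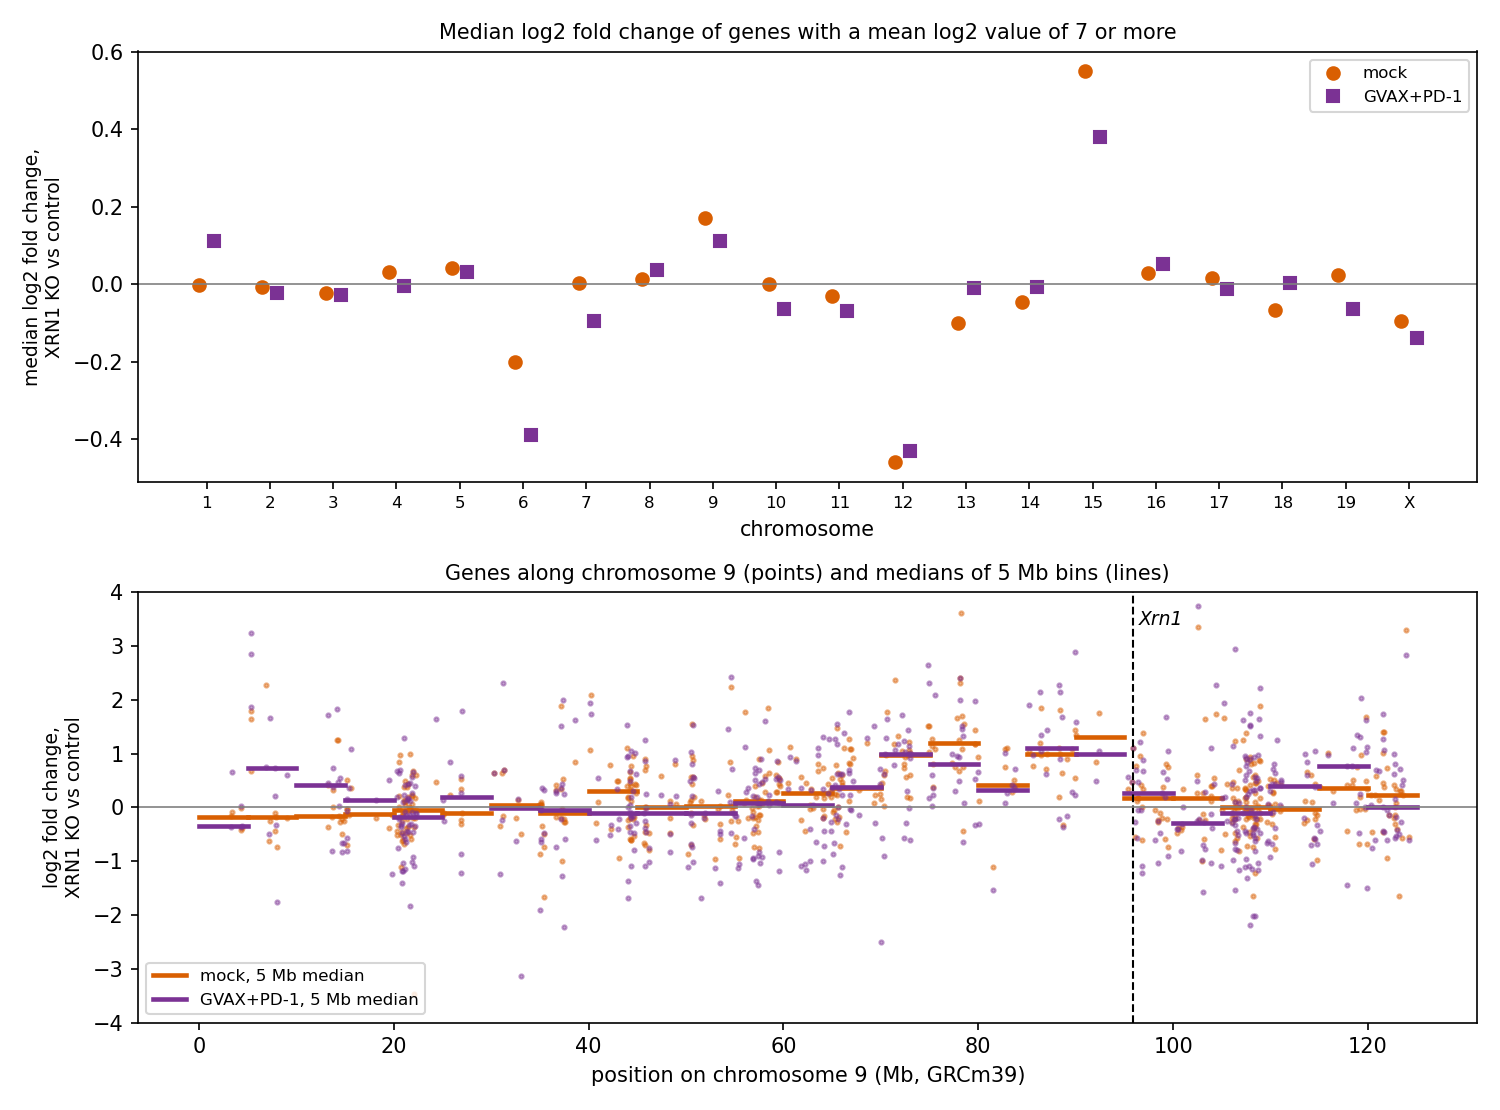
Upper panel: median log2 difference, knockout-labelled against control, of genes with a mean log2 value of 7 or more on each chromosome, under mock (circles) and GVAX plus PD-1 antibody (squares), with chromosome 15 highest and chromosome 12 lowest in both. Lower panel: the same difference for single genes along chromosome 9 (points; position in Mb, GRCm39) with medians of 5 Mb bins (lines) and the position of Xrn1 (dashed line), where 3 of 577 genes lie outside the plotted range.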

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

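The tests of explanations in this part were all chosen after the results they bear on were seen, except the counts over other splits of the libraries. Each result here was picked out because the effect of treatment differed between knockout-labelled and control tumours by the interaction test, with 3 libraries in each of the 4 groups. For the interaction, the residuals of a fit with both main effects and no interaction were reordered over the 12 libraries and added back, which keeps both main effects and evens out the unequal spread of the groups. For the 101 interaction genes, 1 of 100 orders, the real one, gave as many and the highest other gave 2. These orders argue against chance only for groups of equal spread, so they do not exclude it here. In simulated reads with unequal spread, 3.8 unchanged genes were called per run for the interaction. Without XRN1KO_mock replicate 4 the real count was 5. Chance is not excluded for the 16 lists either, since 7 of 100 orders gave as many and the highest other gave 18.

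The positive interactions (log2) with a group of libraries listed at 0, whose size depends on the pseudocount, were 11.4 for Ubd, 10.7 for Gbp8, 9.47 for Gbp10, 9.29 for Serpina3f, 9.1 for Gbp2b, 8.56 for Apol6, 8.14 for Rap1gap2, 7.82 for Klra17, 7.32 for Pacsin1, 7.31 for Ifi44 and 6.6 for Siglech. Those with values in every group were 6.63 for Gbp4, 5.21 for Zbp1, 4.74 for Lck, 3.53 for Irgm1, 3.42 for Irf8, 3.3 for Herc6, 2.65 for H2-Q4, 2.49 for Ifit2 and 2.26 for H2-T23. The negative ones were -6.18 for Tenm4, -2.72 for Car6, -2.62 for Myl9, -2.36 for Shmt1, -2.22 for Megf10, -2.08 for Shisa4, -2.06 for Fscn1, -1.99 for Hmga2, -1.97 for Ptp4a3, -1.87 for Cited1, -1.39 for Tyms and -1.31 for Rrm2. The list medians were 3.54 for interferon-gamma-induced genes, 3.34 for cytotoxic genes, 3.18 for B cell markers, 3.1 for T cell markers, 2.96 for mitochondrial genes, 2.67 for NK markers, 2.34 for MHC class II, 2.18 for macrophages, 2.11 for checkpoints, 1.95 for interferon-stimulated genes, 1.89 for MHC class I, 1.16 for dendritic cells (0.191 with library totals, and -0.594 over the 8 members above 0 in every group), 0.854 for RNA sensing genes (-0.07 with library totals), -0.674 for proliferation, -0.741 for endothelium and -0.774 for hypoxia genes. Scaling to library totals moved the median interaction of all genes by -0.92.

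The first pattern weighed is the rise of interferon-stimulated genes in knockout-labelled mock tumours. Transcripts made by T cells, in step with their number, would give these genes the same share of the treated rise as T cell markers. The share already present under mock was 26.6% (23 to 32.3 over left-out libraries, 33 genes) against 3.48% (2.1 to 4.99) for 20 T cell markers, which argues against that source alone. A response of other cells to signals from T cells need not follow T cell number, so it stays open. For 19 macrophage markers the share was 18.2% (12.7 to 23.7), and since this range meets that of the interferon-stimulated genes, macrophage content stays open. Values near the floor in control tumours are argued against by the 23 interferon-stimulated genes with a control mean of 50 or more, whose median difference was 2.33 (2.05 to 2.59). A response of the tumour cells and a higher output per host cell stay open too, since bulk tissue holds both.

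The next pattern is the higher Xrn1 value in libraries labelled XRN1 knockout. A single library exchanged between knockout-labelled and control, or a pair, is argued against because 0 libraries were out of place in the interferon-stimulated score. The difference between chromosomes 15 and 12 also had 0 out of place. Each of these chromosomes was already seen to separate the libraries, so that difference could not have come out otherwise and adds no test. Leukocytes with intact Xrn1 would add 28.1 units (16.3 to 41.2) under mock, as scaled from Ptprc, or 48.9 (26.7 to 75.4) as scaled from 18 macrophage markers, against an observed 236 (213 to 262). Host cells other than leukocytes also carry intact Xrn1 and were not weighed, so they stay open. Fibroblast and matrix genes had a median difference of 2.39 under mock. For treatment in knockout-labelled tumours, the comparison used for the scaling, their median was 0.31. A gain of a chromosome 9 segment that runs past Xrn1 on both sides is argued against by the 11 genes up to 2 Mb above it, with medians of 0.18 under mock and -0.054 under treatment. An exchange of all labels, a segment that ends at Xrn1 (only 2 genes lie within 2 Mb on its lower side, with medians of 0.41 under mock and 0.52 under treatment) and stabilised or upregulated edited mRNA stay open.

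The last pattern is the shift of chromosomes 12 and 15 and of the chromosome 9 segment. GC content and transcript length are argued against as the whole cause, since each shift kept at least 80.6% of its size after their trend was removed, and leukocyte content is argued against because the treated shifts were at most 0.93 times the mock shifts while the Ptprc difference grew 9.2 times and that of macrophage markers 5.2 times (median). Chromosome 6, which also separated the libraries and was left out of this pattern, went from -0.20 to -0.39, so leukocyte content stays open there. Different chromosome copy numbers in the injected knockout and control cells are a candidate explanation: both chromosomes separated 6 from 6 libraries, with an adjusted exact permutation p of 0.011, and shifted with the same sign at low, middle and high level. The size was less even. On chromosome 15 it was 0.58, 0.50 and 0.15 at these levels under treatment, against 0.46, 0.57 and 0.58 under mock. On chromosome 12 it was -0.35, -0.31 and -0.64 under treatment, against -0.47, -0.44 and -0.51 under mock. The copy number hypothesis was found and tested on the same data, and the editing itself and differences between clones or cell passages were not told apart by any test here.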

How the results depend on the processing

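Alternatives chosen only after the data were seen were quantile normalization, totals without mitochondrial genes, array weights, the mitochondrial share as covariate, and leaving out control_GVAX_PD1 replicate 7 with XRN1KO_GVAX_PD1 replicate 12; the others were planned. No paired analysis was possible because the groups share no replicate numbers. Tests that need counts (DESeq2, voom and edgeR with either scaling) were not run. The cause of a change was not tested unless its construction gives it. Depth is known only roughly, so low genes carry no detection limit. Counts below follow the order: knockout-labelled against control under mock and under treatment, treatment in control and in knockout-labelled tumours, interaction, and the averaged contrasts.

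Across the alternatives, 392 results on named genes gave 9556 values, of which 7918 kept direction and threshold, 1592 kept direction alone and 46 turned. With a pseudocount of 0.1 the interaction had 54 genes and the correlation of knockout-labelled differences between treatments, 0.509 above, was 0.434; with 5 they were 222 and 0.565, and treatment in control tumours had 2 genes. Without a filter (24666 genes) the interaction had 36 and the correlation was 0.484. A minimum of 5 (16526 genes) gave 1 gene in treated control tumours and 0.542, and the stricter filter (12517 genes) 1 gene, 0.647 and Xrn1 under mock at 1.11 (adjusted p = 0.043).

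Library totals shifted the median of all genes by 0.19, -0.73, -0.36, -1.3, -0.92, -0.27 and -0.81 in the 7 contrasts. They gave 1 gene for treatment in control tumours, 8303 (3.91% higher) in knockout-labelled tumours against 1792, of which 1355 were shared in the same direction and 7 turned, 2322 (4.13%) for the interaction and 7643 (2.84%) for averaged treatment. The shares higher were 89.6% of 635 against 72.2%, 20.1% of 5408 against 56.5% and 40.2% of 4290 against 61.1% for the knockout-labelled contrasts, and 66.7% of 15 against 50% for lists in treated control tumours. Xrn1 was at 1.3 (adjusted p = 0.037) under mock and 0.36 (0.44) under treatment. Turned genes were Tbk1 (-0.024), Pfkfb3 (-0.309) and Klf6 (-0.38) for treatment in knockout-labelled tumours and Pan3 (-0.0542) and Pfkfb3 (-0.0771) for averaged treatment. Totals without mitochondrial genes shifted medians by 0.15, 0.00035, -0.25, -0.4, -0.15, 0.074 and -0.33, and gave 1, 3030 (15.9%) and 2601 (10.3%) genes for the treatment contrasts, shares of 85.6% of 738 under mock, 43.6% of 78 for the interaction and 63.6% of 11 lists in treated control tumours, and Xrn1 under mock at 1.26 (0.024). Quantile normalization shifted them by -0.13, -0.26, -0.0016, -0.077, -0.078, -0.24 and -0.037, and gave 3 genes (33.3% higher) in treated control tumours, 162 for the interaction, shares of 44.8% of 4003 and 48.7% of 4141 for the treated and averaged knockout-labelled contrasts, 37.5% of 8 lists in treated control tumours, and Xrn1 under treatment at 0.864 (0.055).

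The melanocyte score was 11.7 at most in control and 12 at least in knockout-labelled libraries, and the mitochondrial share was 44.5% or more in treated knockout-labelled libraries and at most 15.7% elsewhere, so each covariate shares much of a comparison it adjusts. With the melanocyte score the counts were 2, 0, 252 (56.3% higher), 48, 0 and 1 (treatment in control tumours stayed at 0), lists 0 in treated control tumours, 12 and 11 in the averaged contrasts, Xrn1 at 1.05 (0.67) under treatment and 1.06 (0.74) averaged, and the correlation 0.831. Turned genes were Mx2 (-1.34), H2-DMb1 (-0.684) and Asns (0.0953) under mock, Vcam1 (-0.788) under treatment and B2m (-0.228) averaged. With the mitochondrial share the counts were 0 under treatment, 0 for treatment in knockout-labelled tumours, 0 for the interaction, 330 and 0 averaged, lists 11 (81.8% higher), 18 (55.6%), 6, 13 (53.8%), 15 (53.3%), 19 (63.2%) and 12 (58.3%), Xrn1 at 0.649 (0.85) and 0.896 (0.37), and the correlation 0.308. Turned there under treatment were Ighm (-0.548), Hk2 (0.254), Zfp36 (-0.0965), Dusp1 (-0.326), mt-Nd4l (-4.23), mt-Nd2 (-3.63) and mt-Nd6 (-3.92). For treatment in knockout-labelled tumours they were Nnt (2.83), Abca12 (2.52), Slc10a3 (3.3), Ighm (-2.38), Calr (0.388), Ciita (-0.648), Pmel (1.55), Mlana (0.785), Gdf15 (0.556), Eng (0.741), Zfp36 (-0.227), Klf6 (-0.295), mt-Nd6 (-3.91), mt-Nd2 (-3.62) and mt-Nd3 (-3.29). In the averaged contrasts they were Ighm (-0.0193), mt-Nd5 (-1.82), mt-Nd4l (-1.86) and mt-Nd6 (-1.7), and then Vmn2r120 (-0.759), Zbp1 (-0.186), Pdia3 (0.225), Ifi30 (0.269), Pmel (0.692), Gdf15 (0.157), Slc3a2 (0.298), mt-Nd6 (-1.69), mt-Nd3 (-1.39) and mt-Nd2 (-1.66).

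Array weights (0.241 to 3.75) gave 3956 genes under mock, 4 and 3141 for treatment in control and knockout-labelled tumours, 392 for the interaction and 1925 for averaged treatment, and Xrn1 under mock at 1.16 (0.00088). A minimum log2 change of 1 gave 2439 (76.8% higher) and 415 (58.1%) averaged. The 2 groups fitted alone gave 2854 genes and Xrn1 at 1.11 (0.016) under mock, and 1185 and 1.1 (0.11) under treatment. Without control_GVAX_PD1 replicate 7 and XRN1KO_GVAX_PD1 replicate 12 there were 1369 genes under mock, 1240 (49.5%) for averaged treatment, 4 lists in treated control tumours and Xrn1 under mock at 1.11 (0.028).

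In the same order, 2, 6, 0, 5, 8, 4 and 1 lists passed with an estimated correlation and 11, 22, 1, 14, 10, 19 and 10 by fry, against 12, 20, 10, 19, 16, 20 and 18 with the preset value.

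With each library left out, the counts ranged over 200 to 1037, 3338 to 4352, 0 to 1, 522 to 2388, 5 to 219, 3160 to 5163 and 140 to 1019 genes and 11 to 15, 18 to 21, 5 to 12, 17 to 20, 14 to 18, 19 to 20 and 14 to 21 lists. Xrn1 ranged from 0.937 to 1.23 under mock (adjusted p 0.036 to 0.2), 0.832 to 1.3 under treatment (0.011 to 0.072) and 0.973 to 1.21 averaged (0.0014 to 0.0088), and the correlation from 0.457 to 0.533 (SD 0.022). The lowest counts came without XRN1KO_mock replicate 5 (200 under mock) and XRN1KO_mock replicate 4 (522, 5 and 140), and without control_GVAX_PD1 replicate 9 the interaction had 219. Without control_mock replicate 3, control_GVAX_PD1 replicate 7 or 8 the lists in treated control tumours were 6, 5 and 6.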

Other observations

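The list of small nucleolar RNA host genes was tested after its members had been seen, and so were the chromosome and library views given here, while the bound for the list of decay factors was written before its result was seen and the use of its range over left-out libraries was decided after.

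Other genes of the tumours set the groups apart. Atf4 rose in knockout-labelled tumours averaged over both treatments, by 1.22 ± 0.15 (SE, limma, adjusted p = 0.00011). Of the 22 integrated stress response genes 4 rose and 6 fell, the latter including Shmt2 by 1.02 and Phgdh by 0.98, and the list did not pass (adjusted p = 0.13). Endothelial markers were lower as a list (median -1.13, 4 of 15 fell and 2 rose, adjusted p = 0.0043, and adjusted p = 0.39 with an estimated correlation), and Vwf, a clotting factor of endothelium, was an exception that rose by 2.00. Under mock alone the endothelial list had a median of -0.41 and did not pass (camera, adjusted p = 0.35), while its median under treatment was -1.56. Xist, the RNA that coats the inactive X chromosome, was 267 in XRN1KO_GVAX_PD1 replicate 11 and averaged at most 4.53 in the groups without that library, and the sex of the mice is not given in the sources used here.

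A hypothesis was that transcripts removed by nonsense-mediated decay, which XRN1 completes, would be higher in knockout-labelled tumours. The 10 factors of that pathway, which it regulates itself, had a median log2 difference of 0.30 over both treatments, at percentile 93.9 of 10000 random lists matched on level (79.2 to 97 over left-out libraries). The 17 tested entries for host genes of small nucleolar RNAs had a median of 0.36, at percentile 92.4 (66.8 to 97.8). The symbol Snhg4 occurs more than once in this list. A first version of that list had an antisense gene taken in by mistake and lay above the 95th percentile, and the gene was removed after this was seen. Both lie below the 95th percentile, the bound written beforehand for the factors, which is the side that counts against the hypothesis, but both ranges span it, so neither list decides. By treatment the factors were at percentile 81.7 under mock and 97.2 under treatment, and the host genes at 73 and 89.1. Single members did pass over both treatments: 2 factors rose and 0 fell, and 6 host genes rose and 0 fell, led by Snhg16 (2.53, adjusted p = 1.4e-05) and Snhg15 (2.32, adjusted p = 1.1e-06), named after their values were seen. Another of the 6, Snhg5 (1.35), lies in the shifted segment of chromosome 9, so its rise is not separate evidence on decay. Whether XRN1 function was lost in these tumours is itself open, given the Xrn1 values.

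Other splits of the same libraries were counted for each comparison. For the 4 comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. There the real and highest other counts were 751 and 0 genes, and 12 and 17 lists (4 splits with as many), for the knockout-labelled contrast under mock, and 3970 and 36 genes, and 20 and 17 lists, under treatment, with 1 split as large in each of these but the first lists. For treatment in control tumours they were 0 and 1 genes (all 10 splits) and 10 and 11 lists (5 splits), and in knockout-labelled tumours 1792 and 0 genes (1 split) and 19 and 19 lists (2 splits). For the averaged contrasts 100 splits of the 12 libraries were drawn. As many as the 4301 genes of the knockout-labelled contrast came in a share under 0.05 (1 split, highest other 962). So did its 20 lists (2 splits, highest other 20) and the 808 genes of the treatment contrast (1 split, highest other 637). Such splits argue against chance only for groups of equal spread, so they do not exclude it here. The shares also rest on the draw: an earlier draw of 100 held another split with more than 808 genes for the averaged treatment contrast, a share still under 0.05. Nor is chance excluded for the 18 lists of the averaged treatment contrast (6 splits, highest other 20), a count near the bound that fell on its other side in the earlier draw.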
